A study of Mus musculus with 12 samples.

How the data were processed

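Antibody-based profiling of 5-methylcytosine (m5C) in RNA was carried out on the hippocampus of female wild-type C57BL/6 mice aged 3 months (young) and 18 months (aged). Per the labels' protocols, total RNA was fragmented and incubated with a bead-bound m5C antibody from a commercial immunoprecipitation kit, and directional libraries were made from the captured RNA (IP) and from RNA that had not been immunoprecipitated (input). These libraries were sequenced as paired-end reads on an Illumina HiSeq. The 12 libraries were 3 IP and 3 input libraries of each age. The labels do not say whether the 3 samples of an age came from separate animals. The p-values of tests over libraries therefore measure the spread between these samples, which may be partly technical. Those of Fisher's exact tests and of random lists compare genes or peaks with each other and do not measure that spread.

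The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4 and the mouse genome build mm10. The authors deposited 6 peak lists, each belonging to 1 IP library and its own input, so peaks were called per sample and not on pooled samples. Each peak has a start, an end, a strand, a numbered name and a score. The peak names carry the word MACS, a peak caller that compares read pile-ups in an IP with those in a control. Its version, its settings and the way peaks were restricted to mRNA are not given in the sources used here. The score in the deposited lists is the authors' own value per peak. Its lowest value was 50 or 50.01 in each list, and 274 to 684 peaks per list held the same value of 3100, so the scale was saturated at its upper end. Scores were used to describe, rank or filter peaks within a list; only the rule for naming genes combined lists, by averaging a gene's best scores. A spreadsheet of methylated sites that the labels mention was not analysed here.

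No read counts came with the lists. The sequencing depth of each library and the precision of each peak are therefore unknown, and no interval that needs a depth is given. A list with fewer peaks can stem from fewer reads, a weaker immunoprecipitation or fewer modified sites, and the lists alone do not separate these. An IP peak depends on the abundance of the transcript as well as on its modification. Antibody peaks also do not resolve the modified base.

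Peaks were assigned to genes with a table of 21900 protein-coding gene spans of the mouse assembly GRCm38.p6, which is the mm10 build. A peak was given to each gene span it overlapped by at least 1 base. Where spans overlapped, a gene was left out if its unambiguous peaks lay mainly on the other strand; 99.8% of unambiguous peaks lay on the majority strand of their gene. Between 1.70% and 2.01% of the peaks of a list stayed assigned to more than 1 gene. The table holds no exons, and no genome sequence was used. The planned counts of peaks in untranslated and coding parts of the mRNA, and of the base composition of peaks, were therefore not run. In their place, the share of peaks with their midpoint in the first or the last 1000 bases of a gene span of at least 2000 bases was counted, which was chosen after the data were examined. Coordinates are mm10 and count from 1.

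Lists were compared by the Jaccard index, which is the number of bases covered in both lists divided by the bases covered in either, on the same strand. Consensus regions were the union of all peaks that touched or overlapped on the same strand. A region or gene was called aged-only when it had a peak in 3 of 3 aged and 0 of 3 young lists, and young-only in the opposite case. Values per library are given as mean ± SD and were compared by a two-sided exact permutation test. With 3 libraries against 3 this test cannot give a p below 0.1, so no comparison of this kind could pass 0.05. Counts of restricted regions and genes were set against the other splits of the 6 libraries into 3 and 3.

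The 32 gene lists, 23 of pathways and complexes and 9 of cell type markers, were written before the data were examined, as were the main tests, the rule for naming genes and most of the other settings tried. Each list with at least 5 members that had a peak in any library was tested for aged-only and for young-only members with a two-sided Fisher's exact test against all 9749 genes with a peak, with Benjamini-Hochberg adjustment over 60 tests. The rule named the 12 aged-only and 12 young-only genes with the highest mean of the gene's best score, without predicted genes (names of Gm and a number, or ending in Rik). It also named each restricted gene that belonged to a fixed list, the 10 genes with the highest mean score among those with a peak in all 6 lists, and the m5C writers, erasers and readers. A few genes that the rule would name are not reported here. Counts of peaks in the genes of each list and of peaks per gene were added after the data were examined.

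The other settings were the upper part of each list by score (from the median upward), lists of equal length (the 8549 highest-scoring peaks of each list, the length of the shortest), leaving out each library in turn, a reciprocal overlap of 50%, merging within 100 bases, 2 of 3 against 0 of 3 libraries, main chromosomes only, a replicate block, other backgrounds and 10000 random lists. The upper part shortens every list by about the same share, so it does not test the effect of list length. Equal length removes more peaks from the longer aged lists. The region and gene counting was tested on simulated lists. With every planted region detected in every library, 100% of 200 aged-only and 100% of 100 young-only regions were recovered. With a detection chance of 0.9 per library, 77.5% and 70% were recovered, and with a chance of 0.7, 33% and 27%. Missed peaks also made false calls: at 0.9, 155 of 158 aged-only and 70 of 73 young-only calls were true, and at 0.7, 66 of 109 and 27 of 77. Both ages had the same detection chance in the simulation, whereas the real young lists were shorter than the aged ones. These shares therefore do not carry over to the calls below. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.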

Results

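The data described where an m5C antibody enriched RNA fragments over input in the hippocampus of female mice at 3 months and at 18 months of age. There were 3 peak lists per age, 1 for each IP library and its input. The young lists held 9887, 8549 and 10392 peaks and the aged lists 15189, 14008 and 14294. The number of reads behind each list is unknown. The study set young against aged tissue, and the comparisons below ask how many transcripts carried peaks at each age, which ones did so at only 1 age, and whether they belonged to particular pathways or cell types.

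Every aged library had more m5C peaks than every young library. The aged lists held 14497 ± 616 peaks (SD, n = 3) and the young lists 9609 ± 952 (SD, n = 3), a ratio of 1.51 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). Peaks lay in 6665 ± 233 protein-coding genes in aged libraries and in 5292 ± 291 in young ones (n = 3 each, exact permutation p = 0.1). Together the peaks covered 7664 ± 435 kb in aged and 5184 ± 816 kb in young libraries (exact permutation p = 0.1), a difference of 2480 kb that was 252 kb with lists of equal length (exact permutation p = 0.5). Median peak width did not separate the ages, at 221 ± 4.04 bases in aged and 226 ± 6.11 bases in young lists (exact permutation p = 0.4). The direction of the gene count depended on list length. When each list was limited to its 8549 highest-scoring peaks, the aged libraries had peaks in 4339 ± 16.9 genes and the young ones in 4788 ± 159 (exact permutation p = 0.1), so that every aged library then lay below every young one.

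**Figure D1:**
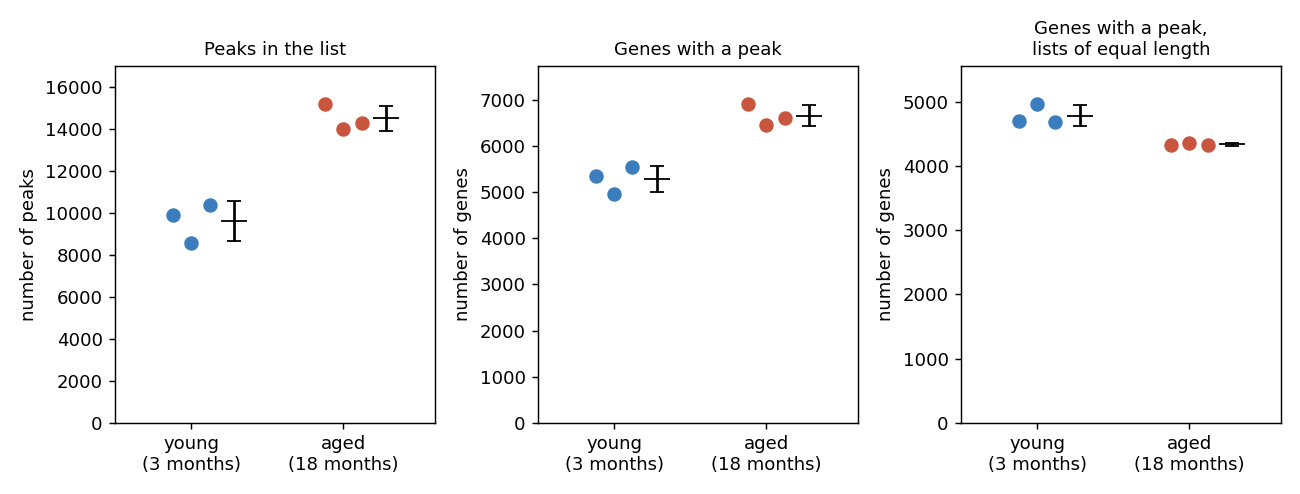
Number of peaks per list (left), number of protein-coding genes with a peak (middle) and number of genes with a peak when each list was limited to its 8549 highest-scoring peaks (right). Each dot is 1 library and the black bars are mean ± SD (n = 3 per age). The aged libraries lie above the young ones in the left and middle panels and below them in the right panel.

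Peaks were present in all 6 lists in 3089 of the 9749 genes that had a peak anywhere. The 10 of these with the highest mean score all reached 3100 or more in every list, where the scale was saturated, so their order has no meaning. They were Gap43, a growth-cone phosphoprotein of axons, Eif3c, a subunit of a translation initiation factor, Cers4, a ceramide synthase, Atp2b1, a plasma membrane calcium pump, Ywhah, a 14-3-3 adaptor, Morf4l1, a chromatin protein, Ubxn4, an endoplasmic reticulum protein, Nmt2, an N-myristoyltransferase, Hnrnpu, a nuclear RNA-binding protein, and Nudcd3. The shared Gap43 region lay on chromosome 16 from 42340473 to 42340651, at the 5' end of the gene span, and that of Hnrnpu on chromosome 1 from 178336953 to 178337797. Of the 4145 regions with exactly 1 peak in each list, 71.4% had identical ends in all 6, so peak widths there were equal at both ages. This limits what the comparison of widths can show. Within a list, peaks in regions common to all 6 lists had higher median scores than peaks found in that list alone, by 3.60 to 5.18 times in the young and 7.53 to 8.66 times in the aged lists.

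On average, lists of the same age resembled each other more than lists of different age. The mean Jaccard index was 0.514 among aged lists (0.511 to 0.518), 0.447 among young lists (0.424 to 0.474) and 0.402 between ages (0.340 to 0.437). Same-age pairs exceeded different-age pairs by 0.0782 on average, and the highest value among the other splits was 0.00617 (exact p = 0.1 over the 10 splits). With lists of equal length the difference was 0.0588. Single pairs overlapped: young replicates 2 and 3 had 0.424, below young replicate 3 with each aged list (0.429 to 0.436), and young replicate 2 had the lowest values with the aged lists (0.340 to 0.362). Of the peaks in a young list, 85.6% ± 1.24 (SD, n = 3) overlapped a region with a peak in at least 1 aged list, and of the peaks in an aged list 66.8% ± 1.96 (SD, n = 3) overlapped one with a peak in a young list. With another list of the same age the shares were 77.7% ± 3.09 in young and 81.9% ± 1.92 in aged lists. These shares depend on how many lists are compared and how long they are, so they do not measure likeness alone.

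Age-restricted regions were found mainly on the aged side. Of 24501 consensus regions, 1258 had a peak in all aged and no young lists, and 156 in all young and no aged lists. Of the aged-only regions, 54.5% lay in genes with a peak in all 6 lists, as did 37.2% of the young-only regions. Of all peaks, at least 9790 of 15189, 9363 of 14008 and 9527 of 14294 in the aged lists lay in such genes. In the young lists at least 7167 of 9887, 6308 of 8549 and 7400 of 10392 did. Restricted regions thus lay in such genes less often than peaks at large, although regions and peaks are different units. At equal list length the counts were 335 aged-only and 306 young-only regions, so the excess on the aged side was 29 regions instead of 1102. With the upper part of each list by score, where the aged lists stayed longer, the counts were 648 against 63.

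At the level of genes, 411 had a peak in all aged and no young lists and 80 in all young and no aged lists. In 305 of the 411 and in 63 of the 80, the same region carried the peak in all 3 lists of the age. The total of 491 compared with 47 to 101 genes for the other splits of the libraries. The balance of aged-only over young-only genes reversed with lists of equal length, to 102 aged-only and 200 young-only genes. Of the original calls, 64 of the 411 and 46 of the 80 still held in that setting. The rest of the 102 and of the 200 genes had a peak at the other age in the lists as deposited, which fell below the cut. That cut removed more peaks from the aged than from the young lists, so the reversal depends on it. Leaving out 1 library relaxes the rule to 2 of 2 on 1 side and gave 516 to 670 aged-only and 102 to 146 young-only genes.

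**Figure D2:**
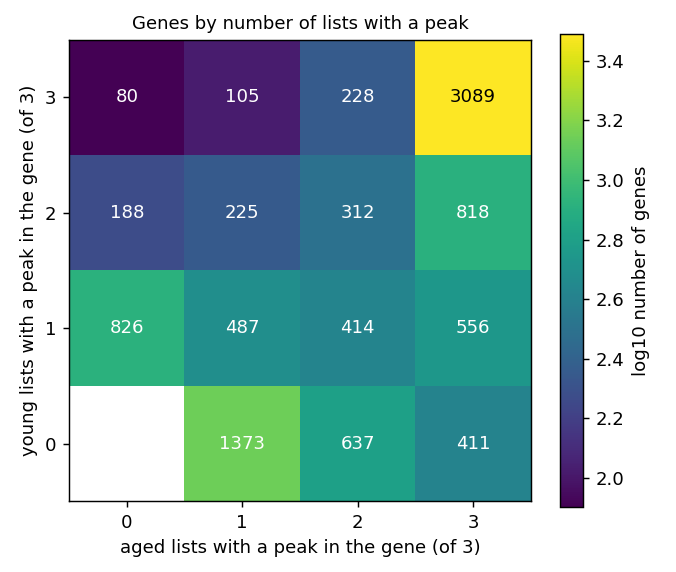
Number of protein-coding genes by how many of the 3 young lists (vertical axis) and of the 3 aged lists (horizontal axis) held a peak in them, with colour on a log10 scale. The upper right square holds the 3089 genes with a peak in all 6 lists, the lower right square the 411 aged-only genes and the upper left square the 80 young-only genes.

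Of the aged-only genes, predicted genes left out, Eif5a, a translation factor, had the highest mean score. It had peaks in the 3 aged lists and none in the young ones, in a region on chromosome 11 from 69916712 to 69917341, with best scores of 66.3, 2834 and 3100. Hoxb3, a homeobox transcription factor, was enriched on chromosome 11 from 96316812 to 96317682 and Eno1, a glycolytic enolase, on chromosome 4 from 150243798 to 150244074. Syn1, a synaptic vesicle phosphoprotein, had its shared region on chromosome X from 20920413 to 20921004. Prkaca, the catalytic subunit of protein kinase A, was enriched on chromosome 8 from 83972978 to 83973232. The others were Prrc2a, Rtn3, Shisa7, Ttyh1, Trappc4, Tmem150b and Fancc. The Fancc peaks lay on chromosome 13 from 63300338 to 63301850 and were also assigned to Aopep, which had peaks in 2 young lists, so their gene is uncertain. Eif5a and Eno1 have processed pseudogenes, and how reads with several matches were handled is not given in the sources used here. With lists of equal length, Eif5a and Ttyh1 had 2 aged and 0 young lists.

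The young-only genes with the highest scores, predicted genes left out, were Ccdc42, H2al1b, Nup62cl, Btaf1, Pramel44, Cct6b, Tmem45a2, Tnfrsf11b, Pramel45, Mylk3, Enoph1 and Spin2g. Ccdc42 had scores of 972, 741 and 703, in a region on chromosome 11 from 68594531 to 68594689. Btaf1, a regulator of the TATA-binding protein, was enriched on chromosome 19 from 36958373 to 36958509. H2al1b, Pramel44, Pramel45 and Spin2g belong to families of similar gene copies, so their peaks are uncertain as to the gene. The Cct6b peaks were also assigned to Zfp830 and lay in a region with peaks in all 6 lists. Predicted genes made up 15 of the 80 young-only genes (18.8%), 10 of the 411 aged-only genes (2.43%) and 99 of the 3089 genes with a peak in all lists (3.20%). The share among young-only genes exceeded that among aged-only genes (Fisher's exact test, two-sided, p = 3.8e-07, a comparison added after the data were examined). This test counts genes as independent, whereas similar copies may share reads, so its p-value may be too small. With lists of equal length, H2al1b had 2 young and 0 aged lists.

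Among the genes that place, remove or bind m5C, peaks were mostly shared by both ages. Of 20 list members, 10 had a peak in at least 1 library, and none was restricted to 1 age by the rule. Nop2, an m5C methyltransferase of ribosomal RNA, the dioxygenases Tet1, Tet2 and Tet3, the m5C-binding protein Ybx1 and the RNA-binding protein Fmr1 had peaks in all 6 lists. Nsun2, the main m5C methyltransferase of mRNA, and the export adaptor Alyref had peaks in 2 aged and 0 young lists. Their best scores in aged replicates 1 and 2 were 51.8 and 182.8 for Nsun2 and 63.6 and 58.0 for Alyref. The lowest listed score was about 50, and the 2 Alyref peaks lay in different regions. Nsun7 and Alkbh1 had peaks in 1 young and 1 aged list each. No list had a peak in Nsun3, Nsun4, Nsun5, Nsun6, Trdmt1, Ybx2, Ybx3, Srsf2, Rad52 or Lin28b. The number of members with a peak was 6.67 ± 1.15 in young and 8.0 ± 1.0 in aged libraries (n = 3 each, exact permutation p = 0.3). For the m6A machinery it was 9.33 ± 1.15 and 14 ± 2.0 of 21 (exact permutation p = 0.1), or 8.0 ± 1.0 and 9.0 ± 1.0 with lists of equal length (exact permutation p = 0.5), and the m6A readers Ythdf1 and Ythdf3 were aged-only. At equal list length Ythdf3 had 3 aged lists and Ythdf1 had 1, Tet2 had 3 young and 1 aged list, Tet1 2 and 3, Nop2 2 and 2, Nsun2 had 1 aged list and Alyref none.

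Neuronal gene groups had more members with a peak in aged libraries, as did all genes together, whose number was 1.26 times as high. In the presynaptic vesicle cycle, 28 of 30 members had a peak, 21 of them in all 6 lists, with 23.3 ± 1.53 members in young and 26.7 ± 0.577 in aged libraries; Syn1 was aged-only. In the postsynaptic density the numbers were 18.7 ± 2.52 and 23.7 ± 0.577 of 25, and Shank1, Homer1, Camk2a and Camk2b had peaks at both ages in every list. Voltage-gated ion channels had 16.3 ± 0.577 young and 21.7 ± 2.31 aged members of 25. GABA receptors and synthesis had 9.67 ± 2.08 and 14 ± 1.0 of 20, with Gad1, which makes GABA, aged-only but not through 1 shared region. Each of these 4 comparisons had an exact permutation p of 0.1. Glutamate receptors had 14.7 ± 0.577 and 18 ± 3.61 of 24 (exact permutation p = 0.4), with Grin2d aged-only and Grin3a young-only. Immediate early genes, which respond to neuronal activity, had 4.0 ± 1.0 and 8.0 ± 1.0 of 20 (exact permutation p = 0.1), and 9 of the 11 with a peak had it in more aged than young lists. Cytoskeleton and axonal transport had 20 ± 1.0 and 22.3 ± 1.15 of 25 (exact permutation p = 0.2), and axon guidance and Wnt signalling 16.7 ± 0.577 and 18.3 ± 1.53 of 25 (exact permutation p = 0.3), where Efnb3 and Dvl1 were aged-only and Sema4d young-only. No neuronal list stood apart from 10000 random lists of genes after adjustment (lowest adjusted random-list p of any list 0.781). On average, members of the 8 lists above had a peak in 0.217 (axon guidance) to 1.09 (immediate early genes) more aged than young lists. The value for all genes was 0.423. The unadjusted random-list p was 0.404 for axon guidance and 0.0622 for immediate early genes. Only 1 list, inhibitory neuron markers, had an unadjusted random-list p under 0.05, at 0.0382. These p-values compare genes and not samples. At equal list length, voltage-gated channels had 15.7 ± 0.577 young and 19 ± 2.65 aged members (exact permutation p = 0.1), but the postsynaptic density had 18 ± 2.0 and 18.7 ± 1.15, glutamate receptors 14.3 ± 0.577 and 14 ± 1.0, and axon guidance 15.3 ± 1.53 and 15 ± 1.0 (exact permutation p = 1 for each). Immediate early genes had 3.67 ± 1.15 and 5.33 ± 1.53 (exact permutation p = 0.3), GABA receptors and synthesis 9.0 ± 1.0 and 11 ± 1.0, the presynaptic vesicle cycle 23 ± 1.0 and 25.7 ± 1.53 (exact permutation p = 0.2 for both), and cytoskeleton 20 ± 1.0 and 21.7 ± 2.31 (exact permutation p = 0.4). In the upper part of the lists by score the aged minus young difference in members was 1 for immediate early genes and 2.33 for GABA, but 5.33 for the presynaptic list and 4 for axon guidance.

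Metabolic and signalling groups also had more members with a peak in aged libraries. Oxidative phosphorylation had 9.0 ± 1.0 young and 14.3 ± 1.15 aged members of 27 (exact permutation p = 0.1). Of its 22 members with a peak, 4 were aged-only, among them the complex I subunits Ndufb3, Ndufb10 and Ndufs3, against 0.927 by chance, which was the lowest p of the 60 list tests (Fisher's exact test p = 0.0125, adjusted p = 0.747). Insulin and mTOR signalling had 9.67 ± 2.08 and 13.7 ± 1.15 of 23, with Akt1 and Irs2 aged-only, and neurotrophin and CREB signalling 11 ± 1.73 and 13.7 ± 0.577 of 20, with Prkaca among its aged-only members. Genes linked to Alzheimer disease had 14.3 ± 3.06 and 19 ± 1.0 of 25, with Picalm aged-only and App, Mapt and Bin1 in all 6 lists. DNA repair and senescence had 5.0 ± 1.0 and 9.33 ± 2.52 of 24, with Atr aged-only, and autophagy and lysosome 9.0 ± 2.0 and 13 ± 0 of 25, with Hexa young-only. Cytosolic ribosomal proteins, whose genes have many pseudogenes, had 13.7 ± 1.15 and 17 ± 1.0 of 30, with Rpl6 aged-only, and translation factors 15.3 ± 1.15 and 17.7 ± 1.15 of 23, with Eif4a2 aged-only. The peaks of Eif4a2 were in part also assigned to Rfc4, and those of Ndufs3 to Kbtbd4. The exact permutation p was 0.1 for each of these groups. At equal list length neurotrophin signalling had 10.7 ± 2.31 young and 13.3 ± 0.577 aged members, Alzheimer-linked genes 13.7 ± 2.31 and 16 ± 0, a difference of 2.33 instead of 4.67, and oxidative phosphorylation 7.33 ± 1.53 and 9.67 ± 3.51 (exact permutation p = 0.1, 0.1 and 0.5). Translation factors (15.3 each) and autophagy (7.0 each) then did not differ in their means, and insulin signalling and ribosomal proteins differed by 0.333 and DNA repair by 0.667 members. In the upper part of the lists by score the aged minus young difference was 5.67 for neurotrophin signalling, 2.67 for Alzheimer-linked genes, 0.667 for DNA repair, 0 for ribosomal proteins and -0.333 for translation factors.

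In other groups the young and aged libraries overlapped or touched. The heat shock and unfolded protein response had 14.7 ± 0.577 young and 16 ± 1.0 aged members of 21, with the stress kinase Eif2ak3 aged-only (exact permutation p = 0.3). The proteasome and ubiquitin ligases had 12.3 ± 0.577 and 13.3 ± 0.577 of 24 (exact permutation p = 0.3), and complement and antigen presentation 5.67 ± 1.53 and 7.33 ± 1.53 of 20 (exact permutation p = 0.5). Oxidative stress defence had 7.67 ± 1.53 and 8.33 ± 1.53 of 20, with catalase (Cat) young-only (exact permutation p = 0.8). Chromatin regulators had 20.7 ± 1.53 and 21.3 ± 0.577 of 24, 18 of them in all 6 lists (exact permutation p = 0.9). The aged mean fell below the young mean at equal list length for heat shock (14 against 14.7), complement (1.67 against 4.0) and chromatin (19 against 20). In the upper part of the lists by score the aged minus young difference was 3.33 for oxidative stress defence, 2.0 for the proteasome, 1.33 for chromatin, 0 for heat shock and -0.667 for complement.

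Among cell type markers, inhibitory neuron markers had 2.67 ± 1.53 young and 6.67 ± 1.53 aged members of 14 with a peak, and astrocyte markers 9.0 ± 1.0 and 12 ± 0 of 15, where Aldh1l1 and Gjb6 were aged-only (exact permutation p = 0.1 for both). Oligodendrocyte and myelin markers had 7.33 ± 1.15 and 9.0 ± 0 of 17 (exact permutation p = 0.1). Excitatory neuron markers had 10.3 ± 1.53 and 12.7 ± 0.577 of 15, oligodendrocyte precursor markers 4.67 ± 1.15 and 6.67 ± 0.577 of 12, and endothelial and mural markers 8.0 ± 1.0 and 9.67 ± 0.577 of 16, where Pecam1 was aged-only (exact permutation p = 0.2 for each). Microglia markers had 5.0 ± 0 and 5.33 ± 0.577 of 16, choroid plexus and ependyma markers 1.67 ± 1.15 and 1.33 ± 0.577 of 14 (exact permutation p = 1 for both), and blood cell markers 0.667 ± 0.577 and 1.33 ± 0.577 of 12 (exact permutation p = 0.6). The microglia difference of 0.333 members was 1.33 in the upper part of the lists by score and 0 at equal list length (4.67 ± 0.577 members at each age). The inhibitory neuron difference of 4 members was 1 in the upper part of the lists and 0 at equal list length, with 2.33 ± 1.53 young and 2.33 ± 0.577 aged members (exact permutation p = 1). Astrocyte markers had 9.0 ± 1.0 and 10.3 ± 1.15 at equal list length (exact permutation p = 0.3). Endothelial and mural markers were then lower in aged libraries, with 7.67 ± 1.15 and 3.33 ± 1.53 (exact permutation p = 0.1), as were oligodendrocyte precursor markers, with 4.33 ± 0.577 and 3.67 ± 0.577 (exact permutation p = 0.6).

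None of the 60 tests of aged-only or young-only genes in the lists passed an adjusted p of 0.05 (Fisher's exact test with Benjamini-Hochberg adjustment), and 1 had an unadjusted p under 0.05. Of the 32 lists, 31 had a higher mean number of members in aged libraries, and 17 had every aged above every young library. At equal list length, 18 were higher, 8 lower and 6 the same. Of the 24 aged-only list members, 9 still had 3 aged and 0 young lists in that setting, among them Syn1, Prkaca, Grin2d, Irs2, Picalm and Aldh1l1. In contrast, 4 had a peak in no list then, namely Gad1, Gjb6, Eif2ak3 and Pecam1. Ndufb3, Akt1 and Atr had 1 aged list each, and Ndufb10 and Ndufs3 had 2. Of the 4 young-only list members, Grin3a still had 3 young and 0 aged lists, Hexa and Sema4d had 2 young lists and Cat had 1.

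Counting peaks instead of genes, 26 of the 32 lists had a higher mean in aged libraries at equal list length and 5 a lower one. This count was added after the data were examined. Presynaptic vesicle cycle genes held 58.7 ± 13.6 peaks in young and 109 ± 1.0 in aged lists as deposited, and 52.7 ± 7.02 and 79.3 ± 5.51 with lists of equal length (exact permutation p = 0.1 for both). Cytoskeleton and axonal transport genes held 86.3 ± 16.8 young and 119 ± 13.9 aged peaks with lists of equal length, and postsynaptic density genes 41.3 ± 5.69 and 52 ± 3.0 (exact permutation p = 0.1 for both). Some other neuronal lists differed less at equal length: voltage-gated channels held 39 ± 5.0 and 44.7 ± 0.577 peaks (exact permutation p = 0.2), axon guidance 29 ± 2.0 and 29.7 ± 2.08 (exact permutation p = 0.8), and immediate early genes 8.33 ± 3.21 and 8.33 ± 1.53 (exact permutation p = 1). Endothelial and mural markers held 11 ± 2.0 young and 13.3 ± 0.577 aged peaks as deposited (exact permutation p = 0.3), but 10 ± 2.65 and 4.0 ± 1.73 with lists of equal length (exact permutation p = 0.1).

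**Figure D3:**
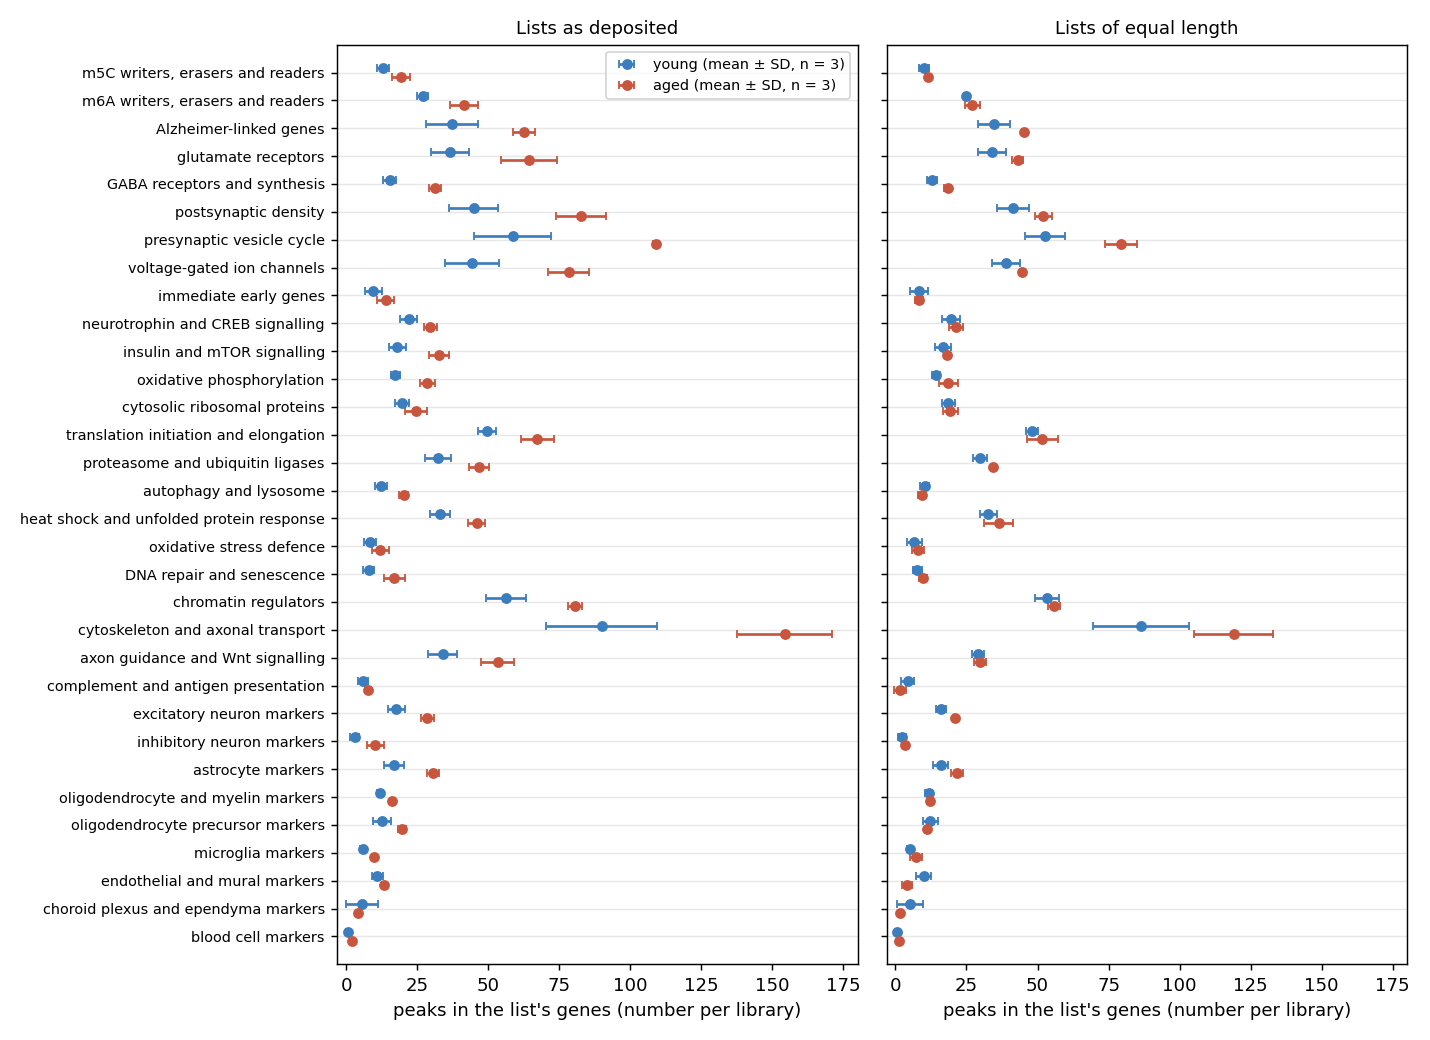
Number of peaks in the genes of each of the 32 lists, with the lists as deposited (left) and limited to 8549 peaks each (right). Dots are means and bars SD over 3 libraries per age, blue for young and red for aged. Presynaptic vesicle cycle genes lie higher in aged libraries on the right (79.3 against 52.7), while endothelial and mural markers are lower (4.0 against 10).

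The share of peaks near the start of genes was slightly higher in aged libraries, by an amount that depended on the setting. The midpoint was in the first 1000 bases of the gene span for 9.66% ± 0.615 of peaks in aged and 8.75% ± 0.302 in young libraries, and in the last 1000 bases for 8.24% ± 0.298 and 8.78% ± 0.235 (SD, n = 3 each, exact permutation p = 0.1 for both). The difference of 0.902 percentage points at the start was 0.390 in the upper part of each list by score (exact permutation p = 0.5), 1.29 with lists of equal length (exact permutation p = 0.1) and 0.556 without aged replicate 2 to 1.14 without aged replicate 3. That of -0.540 at the end was -0.856 in the upper part of the lists, -0.753 at equal length and -0.108 with windows of 500 bases (exact permutation p = 0.5). This is a position along the unspliced gene span, since exons and untranslated regions were not annotated here.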

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

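The tests of sequencing depth, of the other splits and of unlisted peaks within genes and over all stretches were chosen after the result was seen; the other tests in this part were not. Groups of 3 libraries are too small for a test of single outlying samples, and none was made.

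Peak numbers that are not part of the lists were the first signal outside the main measurement. The peak names are numbered in order of position, and the numbers run far beyond the peaks listed. At least 275102 numbered peaks were missing from each list, and the listed peaks made up 2.84% ± 0.589 of the highest number in young and 4.14% ± 0.142 in aged libraries (SD, n = 3 each, exact permutation p = 0.1). The highest number itself was 344480 ± 51578 in young and 350469 ± 16056 in aged libraries.

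These numbers bear on the larger aged lists. More background outside genes in the young libraries stays open: the density of unlisted peaks in 39 gene-poor stretches was 0.934 times as high in aged as in young libraries, with a spread of 0.147 (exact permutation p = 0.5). Young replicates 2 and 3, with 111.9 and 108.5 per Mb, lay above every aged library (88.7 to 99.5 per Mb) and young replicate 1, with 84.8 per Mb, below. An overlap of the ages was set beforehand to count against this explanation, but it rests on that 1 library; how to read it was settled after the values were seen. Within genes the density of unlisted peaks was 179.6 ± 20.6 per Mb in young and 209.4 ± 4.87 in aged libraries (exact permutation p = 0.1), and over all stretches 130.6 ± 20.2 and 131.0 ± 6.09 (exact permutation p = 1). Deeper sequencing of the aged libraries stays open too. The ratio of highest peak numbers, aged over young, was 1.02 with a spread of 0.159, below the 1.3 that depth alone was taken to need. Within the young libraries, however, the highest number did not follow list length throughout (284989 for the list of 9887 peaks, 371784 for that of 8549 and 376666 for that of 10392). In the aged libraries it rose with list length (331930 for 14008 peaks, 359652 for 14294 and 359825 for 15189). Whether the highest number tracks depth is therefore unknown. That the number should follow list length was asked only after its values were seen. Weak peaks missed in the young libraries, as from a weaker immunoprecipitation, are a candidate explanation: aged-only regions had a median score percentile of 39.0 within the aged lists, against 80.6 for regions found in all 6 lists, although young-only regions ranked as low in their own lists (37.1). A difference with age in m5C or in transcript abundance remains open too and was not tested.

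The real split gave 491 age-restricted genes and 1414 age-restricted regions, against at most 101 and 240 for the other splits, so 1 of 10 splits reached the real value in each case. The splits are too few for a share under 0.05.

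Peaks on chromosome Y were present in lists from female mice. There were 23 in total, 2 to 7 per list, between positions 90754513 and 90844074, and none overlapped a protein-coding gene span. No genome sequence was used here, so it was not examined whether reads at these positions also match another chromosome. These peaks are therefore no measure of the sex of the mice.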

How the results depend on the processing

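List length turned the direction of several results. The peaks per gene, gene-span positions, peaks per gene list, single-gene peaks and lists without predicted genes were chosen after seeing the data; the other alternatives were planned. With lists of equal length, the aged minus young difference was -449 genes with a peak, 0.667 bases of median width, 335 aged-only and 306 young-only regions (29 more on the aged side), and 102 aged-only and 200 young-only genes (-98). In the upper part of each list by score, where the aged lists stayed longer, there were 648 aged-only and 63 young-only regions (585 more) and 273 and 27 genes. With 2 of 3 against 0 of 3 libraries there were 3645 and 674 regions (2971 more), and 1048 and 268 genes (780 more), as the looser rule implies.

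Leaving out 1 library also loosens the rule on its side. Aged-only regions ranged from 1500 to 2148, young-only regions from 210 to 330 and their difference from 1171 to 1928. Aged-only genes ranged from 516 to 670, young-only genes from 102 to 146 and their difference from 380 to 547. Aged-only genes exceeded 1.5 times the main count without young replicate 3 (670), aged replicate 2 (649) or aged replicate 3 (635). The other summary results kept their direction without each library, and no gene list passed the adjusted threshold under any alternative in which the lists were tested.

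Aged minus young members with a peak turned negative with lists of equal length for glutamate receptors and axon guidance (-0.333 each), the heat shock response and oligodendrocyte precursors (-0.667 each), chromatin regulators (-1), complement (-2.33) and endothelial markers (-4.33), and in the upper part of the lists for translation factors (-0.333), complement (-0.667) and endothelial markers (-2). Peaks in list genes did so at equal length for autophagy (-1), oligodendrocyte precursors (-1.33), complement (-2.67) and endothelial markers (-6). Without 1 library, the member difference ranged from -0.167 to 1.33 for oxidative stress defence and for chromatin regulators and from -0.667 to 0.333 for choroid plexus markers, whose peaks ranged from -3.67 to 1.83.

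Reciprocal overlap, merging within 100 bases, main chromosomes, single-gene peaks and leaving out predicted genes left every summary count they were run on within 1.5 times. The aged minus young number of lists of a named gene was another for 25 genes at equal length, 42 in the upper part of the lists and 4 with single-gene peaks (Cct6b, Eif4a2, Fancc and Ndufs3). Leaving out 1 library changed it for 32 to 53. By construction, leaving out an aged library can only lower this number and leaving out a young library can only raise it.

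With the replicate block the differences of 4888 peaks and 1373 genes are unchanged by construction, and the exact sign-flip p was 0.25, the smallest that 3 pairs allow. Each library's deviation correlated best with its own number, but at 0.0181 or less. With 3 pairs, these small values neither show nor exclude a link between samples of the same number. Counts of peaks by mRNA feature, by bases overlapped, and of base composition were not run, for lack of exons and sequence. Depth is unknown, so the causes of these shifts were not tested.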

Other observations

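The tests in this part were written before their results were seen, while the patterns they bear on had been noticed in the same data. The genes named by peaks per gene were chosen after their values were seen, and the bound for weak peaks was reconsidered after its value was seen.

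Among genes with a peak in all 6 lists, the 10 with the highest aged minus young difference in peaks per gene were Kalrn, Syne1, Macf1, Ryr2, Dst, Ank2, Tpr, Sptan1, Itpr1 and Kif1b. All such genes together had 2.33 ± 0.200 peaks each in young and 3.19 ± 0.0746 in aged libraries, a ratio of 1.37. A ranking by difference therefore favours genes with many peaks, which can follow this general rise. Kalrn, an exchange factor of dendritic spines, had 12 ± 2.0 peaks in young and 23.7 ± 3.21 in aged libraries (SD, n = 3 each). Ank2, an ankyrin of axons, had 7.0 ± 4.0 and 15 ± 4.36, Sptan1, a spectrin, 6.67 ± 1.15 and 14.3 ± 0.577, and Kif1b, a kinesin motor, 7.67 ± 1.53 and 15 ± 1.73. Ryr2 and Itpr1, which release calcium from internal stores, had 20.7 ± 1.53 and 31 ± 4.0, and 15.7 ± 5.13 and 23 ± 2.65. With lists of equal length, Sptan1 had 5.67 ± 1.53 young and 11.3 ± 0.577 aged peaks, Kalrn 11 ± 1.0 and 14 ± 0, Ank2 6.33 ± 3.51 and 10.3 ± 2.89, Kif1b 7.67 ± 1.53 and 10 ± 1.73, and Itpr1 13.3 ± 3.06 and 17.7 ± 1.53, while Ryr2 had 20 ± 1.73 and 19.3 ± 2.31, Syne1 18 ± 4.36 and 18 ± 1.73, and Macf1 18.3 ± 2.08 and 20 ± 1.0. Of 3089 genes, 540 had more peaks in every aged than in every young library and 11 had fewer, against at most 63 in 1 direction for other splits. With lists of equal length the numbers were 122 and 95, against at most 48.

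The 5 genes at the other end were Zfp978, Zfp991, Tcp10c, Sp140 and Zfp993. Zfp978, Zfp991 and Zfp993, zinc finger genes in a cluster on chromosome 4, had 5.0 ± 1.73, 4.33 ± 1.15 and 5.0 ± 0 peaks in young libraries and 2.33 ± 1.53, 1.67 ± 0.577 and 3.0 ± 1.0 in aged ones. Such clustered genes are similar to each other in sequence, so their peaks are uncertain as to the gene.

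With lists of equal length fewer genes carried a peak in aged libraries. A candidate explanation is more peaks per gene in the same genes. Genes with a peak in all 6 lists had 2.25 ± 0.0139 peaks each in aged and 2.16 ± 0.0471 in young libraries at equal list length, a ratio of 1.04, with every aged above every young library. At a fixed number of peaks, fewer genes mean more peaks per gene on average, so the test says only that these shared genes took part. Whether the cause lies in the tissue or in the immunoprecipitation was not tested.

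Young-only genes held many predicted genes, 15 of 80. Weak peaks near the calling floor stay open: the peaks of young-only genes had a mean median score percentile of 30.5 in the young lists, with 25.5 to 34.5 in single lists. This is above the 25 set beforehand, but that bound was too low to exclude weak peaks, since regions in all 6 lists stood at 72.5 in the young lists; the peaks of aged-only genes ranked as low in the aged lists (32.0). Reads shared between near-identical copies or pseudogenes stay open too. A first comparison, of the shares of predicted genes themselves, restated the pattern and was replaced by a search for similar peaks nearby. Of the peaks of young-only genes, 20.1% had a peak of near-identical width and score in another gene within 5 Mb, against 16.6% for aged-only genes in the aged lists. The share was higher in every young list but did not pass the test on pooled peaks (Fisher's exact test p = 0.162). The pooled peaks came from the same genes in several lists, so they are not independent. For genes with a peak in all 6 lists the share was 10.2% to 10.9% in the young lists and 13.9% to 14.4% in the aged lists. Young-only genes thus stood further above the shared genes of their own lists than aged-only genes did, a difference that was not tested. No genome sequence was used to look for copies, and a biological explanation was not tested.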
